A study of Homo sapiens with 16 samples.

How the data were processed

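The series comprised 16 samples of 2 prostate cancer cell lines, LNCaP (androgen-sensitive) and PC-3 (androgen-independent). Peak lists of 12 libraries were analysed: HOXB13, HDAC1 and HDAC3 ChIP-seq and ATAC-seq of LNCaP, and HOXB13 and H3K27ac ChIP-seq of PC-3. The LNCaP H3K27ac libraries (4 samples) were not analysed here. Per the labels' protocols, LNCaP cells were infected for 7 days with a control shRNA vector (pGIPZ), a HOXB13 shRNA, or the HOXB13 shRNA together with a lentivirus carrying HOXB13-WT or HOXB13-G84E. The ATAC-seq libraries were made from 50000 cells, per the labels' protocols. Groups were taken from the labels, and each group held 1 library.

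Bowtie2, HOMER 4.2 and the hg19 genome build are named in the submitters' processing notes. Per the file headers, the authors called peaks per library with the HOMER findPeaks program, with no input library on the command line and a false discovery rate of 0.001. For the 10 HOXB13, HDAC1, HDAC3 and ATAC-seq lists the factor style was used, which gives peaks of 1 fixed width per library. Those peaks had to exceed the surrounding 10000 bp 4-fold at a local Poisson p of 0.0001. For the 2 PC-3 H3K27ac lists the histone style was used, in which windows of 1000 bp are stitched into regions of varying width. The signal in each deposited list is the normalized tag count, which is the number of tags in the peak scaled to a library of 10000000 tags, per the file headers. The deposited findPeaks score and the deposited fold over the local background are the authors' own values for each peak. The score was used only to rank peaks within a list, and the fold only to describe lists.

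Total tags per library, with M for mega, ranged from 13.5 M (PC-3 H3K27ac, HOXB13 shRNA) to 47.2 M (LNCaP HOXB13 ChIP, HOXB13 shRNA). Whole tags were recovered from the normalized tag counts and the library totals in the headers. All values under 10 came out whole within 0.1 tags (100%). With 1 library per group, no count test between conditions was possible, and no p-value is given. The estimated fragment length and peak width differed between libraries compared with each other. The estimated HDAC3 fragment length was 146 bp in the control and 364 bp in the knockdown library. For HDAC3 the peak width was 471 bp in the control and 365 bp in the knockdown library, and for ATAC-seq it was 96 and 111 bp. A tag ratio at a fixed-width peak therefore includes the difference in width. Tag densities (tags per bp) are given beside the medians. The log2 ratio of widths was −0.18 for HOXB13 after knockdown and 0.047 for G84E over WT. Ratios at named regions other than H3K27ac loci were left uncorrected for width. No list of excluded regions is recorded in the headers, so satellite, mitochondrial and unplaced sequences remained in the lists.

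Peaks were counted as shared when they overlapped by at least 1 bp. Shares are given with Wilson 95% intervals, differences of shares with Newcombe 95% intervals, and medians with intervals from 1000 bootstrap resamples of peaks. Ratios at named regions have exact (Clopper-Pearson) intervals from the recovered tags. Those regions were picked as the most extreme, and their intervals are not adjusted for that choice. All these intervals cover counting error or the spread between peaks of 1 library, not the spread between cultures. Where 1 peak met several, the highest normalized tag count was used. H3K27ac regions linked by overlaps were first summed into loci. Chance overlap was estimated from 100 random placements of peaks within their chromosomes. The percentile of a class median was taken among 10000 random sets of peaks matched on 10 equal groups of control tag count. Differences between peaks with and without HOXB13 were also standardised over those 10 groups, weighted by the peaks with HOXB13, with intervals from 200 resamples.

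Comparisons, overlap rules and the following alternatives were fixed before the data were examined: peak centres within 100 bp (500 bp for H3K27ac), overlap of at least 50% of the shorter peak, the better-scoring 50% of every list, a common floor of tag count, equal numbers of peaks, autosomes and X only, standardisation for peak strength in the retention comparisons, centring of ratios, and another definition of the HOXB13 class. Standardisation of gains and of tag changes, and tag density, were added after the data were seen. Named regions followed a rule fixed beforehand. For each comparison of a pair of libraries these were the 5 regions with the largest rise and the 5 with the largest fall among those called in both, with a mean tag count of at least the control median, and the 5 strongest called in each library alone. Coordinates are hg19, as in the files. The lists pair no peaks with genes. No hg19 sequence or annotation was used here, so gene lists fixed beforehand, the HOXB13 motif, nearest genes and signal over the HOXB13 exons were not analysed here.

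The calculations were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. The overlap code was tested on simulated peaks, and 0 of 60 overlap tables differed from a direct count. The standardised retention difference was tested on the 33964 control HDAC3 peaks in 20 simulations. A simulated difference of −10 points was recovered as −10.0 points on average, and no difference as −0.081 points.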

Results

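HOXB13 is a homeobox transcription factor of the prostate lineage, and HDAC3 is the histone deacetylase of the NCOR/SMRT corepressor complexes. The series mapped HOXB13, HDAC1 and HDAC3 by ChIP-seq and open chromatin by ATAC-seq in LNCaP prostate cancer cells, and HOXB13 and acetylation of histone H3 lysine 27 (H3K27ac, a mark of active promoters and enhancers) in PC-3 prostate cancer cells. HOXB13 was lowered with a short hairpin RNA, and in LNCaP it was re-expressed as the wild-type protein (WT) or as the G84E variant. Each of the 12 libraries analysed stood alone in its group, so there were no replicates and every interval covers counting error or the spread between peaks only. The LNCaP HOXB13 lists held 91430 peaks in the control (34.4 M tags, where M stands for mega), 22864 after knockdown (47.2 M), 190879 with WT (40.3 M) and 191796 with G84E (44.2 M). HDAC3 had 33964 peaks in the control (21.6 M tags) and 30993 after knockdown (26.3 M), and HDAC1 had 16632 in the control (14 M). ATAC-seq gave 37073 peaks in the control (36.1 M tags) and 29932 after knockdown (25.5 M). In PC-3, H3K27ac covered 50352 regions in the control (15.0 M tags) and 49632 after knockdown (13.5 M), and HOXB13 had 70766 peaks (27.7 M).

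The first comparison checked the knockdown at the protein that was immunoprecipitated. Few control HOXB13 peaks were called again: 1353 of the 91430 control peaks, 1.48% (95% CI 1.40 to 1.56), had a peak in the HOXB13 shRNA library. The share of tags lying in peaks was 9.17% in the control and 2.13% after knockdown. Retention was 0.787% in the weakest and 4.27% in the strongest of 10 equal groups of control peaks. The few retained sites differed from the lost ones in which other lists had a peak there. Some of the retained sites may be regions called in most libraries, as no input library was used in calling. Among HDAC3 peaks called in both HDAC3 libraries, 623 had a retained and 5570 a lost HOXB13 peak. Without regions called in 9 or more lists, 192 and 4050 were left. Of the retained sites, 31.8% had an ATAC peak, 45.5% an HDAC3 peak and 32.8% an HDAC1 peak, against 9.95%, 12.9% and 1.48% of the lost sites, without matching on strength. The retained sites were also stronger, with a median normalized tag count of 9.60 against 7.28. Of the 22864 peaks called after knockdown, 5.92% lay at control HOXB13 sites, 3.39-fold over random placement, with 3.27% for close centres and 2.73% with equal numbers of peaks.

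The largest fall among regions called in both libraries was on chromosome X at 88462180 to 88462470, where the normalized tag count was 66.9 in the control and 5.30 after knockdown (log2 ratio −3.66, 95% CI −4.32 to −3.06). The next was on chromosome 20 at 44044615 to 44044905 (57.9 and 5.51; log2 ratio −3.39, 95% CI −4.04 to −2.80), where ATAC peaks were called in the control and after knockdown. The largest rise was on chromosome 11 at 11268117 to 11268407 (10.5 and 75.6; log2 ratio 2.85, 95% CI 2.36 to 3.39), a region called in 8 of the 12 lists. The strongest peaks called in the control alone included chromosome 10 at 42391552 to 42391842 (1431.5 normalized tags), and those called after knockdown alone included chromosome 6 at 58779098 to 58779354 (650.1 normalized tags). Each of that pair had regions of both PC-3 H3K27ac lists over it. Close to the second, a peak on chromosome 6 at 58778636 to 58778926 was called in the control alone, with 726.1 normalized tags. The peak called there after knockdown alone is therefore no sign of new signal in that region. With equal numbers of peaks in both lists the retained share was 2.73%, and with peak centres within 100 bp it was 0.818%.

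Re-expression asked whether the introduced protein returned to the sites held before knockdown. Both forms did so at most of them when the full lists were used: WT HOXB13 occupied 67.4% of the control sites (95% CI 67.1 to 67.7) and G84E 63.2% (62.9 to 63.6). These shares depended on the list lengths and were 52.1% and 48.3% with equal numbers of peaks. Among the control sites 54.3% were found with both forms, 13.2% with WT alone, 8.99% with G84E alone and 23.6% with neither. The strongest 10% of control sites were almost all reoccupied, 97.8% with WT and 96% with G84E, and the weakest 10% at 43.7% and 42.3%. At shared peaks the median log2 ratio of normalized tag counts to the control was 0.17 for WT (95% CI 0.16 to 0.17) and 0.016 for G84E (0.012 to 0.023), and as tag density 0.25 and 0.052.

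**Figure D1:**
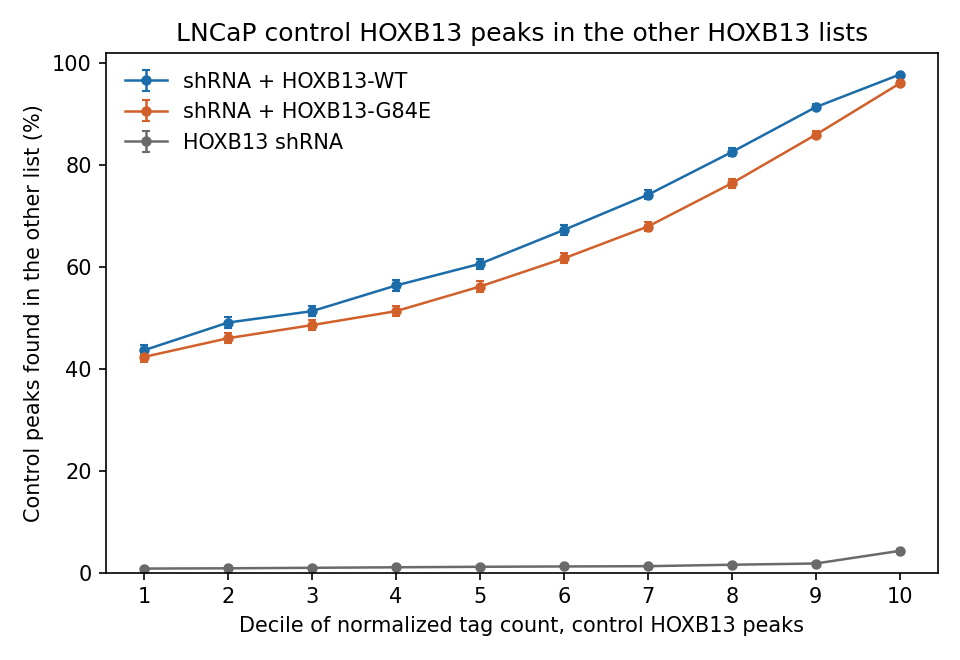
Share of LNCaP control HOXB13 peaks (y axis, percent) found in each other LNCaP HOXB13 list, by decile of the control normalized tag count (x axis), with Wilson 95% intervals. With WT the share runs from 43.7% to 97.8%, with G84E from 42.3% to 96%, and with the shRNA alone from 0.787% to 4.27%.

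With each re-expressed form many peaks were also called outside the control set. WT had 129240 peaks away from control sites, with a median normalized tag count of 5.96 against 9.93 at the 61639 peaks on control sites. Of those additional peaks 1.86% had a control ATAC peak and 2.71% a control HDAC3 peak, against 11.9% and 16% of the WT peaks on control sites, without matching on strength. For G84E the 133971 additional peaks had a control ATAC peak at 1.24% and an HDAC3 peak at 1.94%. Of the additional WT peaks 55496 were also called with G84E. Both libraries had more tags than the control (40.3 M with WT and 44.2 M with G84E against 34.4 M). They also had more of their tags in peaks (17.1% and 15.6% against 9.17%). Some additional peaks may therefore be sites that the control library fell short of calling. With the same number of peaks taken from every list, WT reached 52.1% and G84E 48.3% of the control sites.

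WT and G84E were then compared with each other. The forms shared 55.0% of the WT peaks (95% CI 54.8 to 55.3) and 54.8% of the G84E peaks (54.6 to 55.0), from 26.4% of the weakest to 96.7% of the strongest 10% of WT peaks. At the 105060 WT peaks shared with G84E, G84E tag counts were slightly lower, with a median log2 ratio (G84E over WT) of −0.13 (−0.18 as tag density) and a range of −0.88 to 0.64 from the 5th to the 95th percentile. The share of tags in peaks differed between the libraries by the same log2 ratio, −0.13 (17.1% with WT and 15.6% with G84E). A log2 ratio below −1 was found at 2.84% of sites and one above 1 at 0.815%, and with ratios centred on their median 1.48% were below −1. The median log2 ratio fell with the mean tag count of the site, from 0.0029 in the weakest to −0.29 in the strongest of 10 equal groups. Only peaks called in both lists enter, which limits the ratio in the weakest groups, so part of this trend may follow from the selection.

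Peaks called with only 1 form differed in how often a control HDAC3 or ATAC peak lay there. Without replicates the overlap that repeated libraries of 1 form would give is not known. A peak called with 1 form alone therefore need not be a site that the other form left unoccupied. Of the 85819 peaks found with WT alone, 4.23% had a control HDAC3 peak and 3.28% a control ATAC peak, against 2.13% and 1.50% of the 86734 peaks found with G84E alone. The differences were 2.11 percentage points (95% CI 1.94 to 2.27) for HDAC3 and 1.79 (1.64 to 1.93) for ATAC, while the median normalized tag counts of both groups were alike (5.46 and 5.43). At shared peaks the median log2 ratio was −0.32 where a control ATAC peak lay and −0.10 elsewhere. The strongest rises with G84E were on chromosome 12 at 90287045 to 90287319 (4.72 with WT and 17.0 with G84E; log2 ratio 1.85, 95% CI 1.11 to 2.66) and on chromosome 5 at 120326768 to 120327042 (4.47 and 15.4; log2 ratio 1.78, 95% CI 1.02 to 2.62). The strongest falls were on chromosome 2 at 217357361 to 217357635 (19.4 and 4.30; log2 ratio −2.17, 95% CI −2.98 to −1.43) and on chromosome 1 at 121218064 to 121218338 (19.6 and 4.75; log2 ratio −2.04, 95% CI −2.81 to −1.34). The amount of each protein was not measured in these libraries.

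Overlap of the control HOXB13 list with the deacetylases was larger for HDAC3 than for HDAC1. Of the control HDAC3 peaks 36.1% (95% CI 35.5 to 36.6) had a control HOXB13 peak, 15.3-fold over random placement. For HDAC1 the share was 10.7% (10.2 to 11.1), or 5.76-fold. Control ATAC peaks had a control HOXB13 peak at 26.1%, 21.7-fold over random placement, so the HDAC3 fold was not above that of accessible sites. After HOXB13 knockdown the HOXB13 list met 6.29% of the control HDAC3 peaks (6.03 to 6.55) and 11.6% of the HDAC1 peaks (11.1 to 12.1), so the overlap with HDAC1 did not fall with HOXB13. The HDAC3 share rose from 27.7% in the weakest to 45.7% in the strongest 10% of HDAC3 peaks, and the HDAC1 share from 8.35% to 17.3%. Seen from HOXB13, 13.4% of its control peaks had an HDAC3 peak, 10.3% an ATAC peak and 1.94% an HDAC1 peak. The strongest 10% of HOXB13 peaks had HDAC3 at 38.2% and ATAC at 30.6%. The shares depended on the overlap rule and the list lengths: with peak centres within 100 bp they were 19.6% for HDAC3 and 3.67% for HDAC1, and with equal numbers of peaks 19.8% and 2.95%. The HDAC3 fold over random placement was 31.6 with close centres and 44.2 with equal numbers, and the HDAC1 fold 5.97 and 8.31.

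HDAC3 was next compared between control and HOXB13 knockdown, to ask whether its occupancy depended on HOXB13 where both were bound. Of the control peaks 47.7% (95% CI 47.1 to 48.2) were retained, and 47.8% of the knockdown peaks (47.2 to 48.3) had no control peak, against 21.3% and 76.6% with peak centres within 100 bp. Loss and gain were concentrated among weak peaks, with retention at 20.5% in the weakest and 86.1% in the strongest 10%, and the overlap that unchanged libraries would give is not known without replicates. Control peaks with HOXB13 were retained at 50.6% and those without at 46.0%, a difference of 4.57 percentage points (95% CI 3.46 to 5.67). At equal HDAC3 strength no difference was detectable (−0.191 points, 95% CI −1.22 to 0.739). The new HDAC3 peaks lay mainly away from HOXB13. Among knockdown peaks, 53.6% of those without a control HOXB13 site were new against 32.7% of those with one, a difference of −20.9 percentage points (95% CI −22.1 to −19.7), or −16.4 at equal strength (−17.5 to −15.3) and −12.4 in the better-scoring 50% of the lists. A control HOXB13 peak lay at 38.3% of retained, 34.0% of lost and 18.9% of gained HDAC3 peaks.

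**Figure D2:**
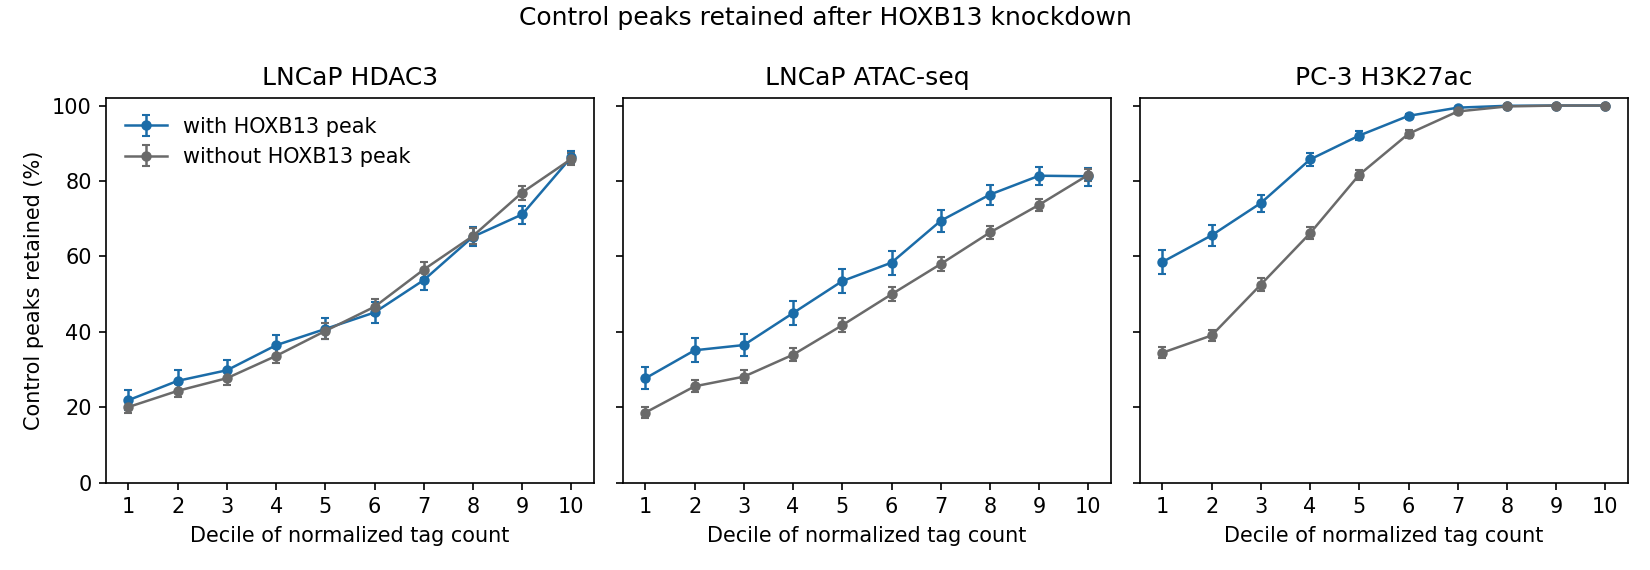
Share of control peaks retained after HOXB13 knockdown (y axis, percent) by decile of the control normalized tag count (x axis), for LNCaP HDAC3, LNCaP ATAC-seq and PC-3 H3K27ac, with and without a control HOXB13 peak of the same cell line and with Wilson 95% intervals. HDAC3 retention runs from 20.5% to 86.1% over all peaks, with the classes close together, while ATAC and H3K27ac peaks with HOXB13 lie above those without over most of the range.

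HDAC3 retention also varied with the strength of the HOXB13 site. The HDAC3 peaks with HOXB13 were divided into 5 equal groups by HOXB13 tag count. Retention relative to HDAC3 peaks of equal strength without HOXB13 was 5.40 percentage points higher in the weakest HOXB13 group. The differences in the next groups were 1.60, −0.245, −3.55 and −4.24. Without matching on strength, the strongest group was retained less often than peaks without HOXB13 only at HDAC3 peaks with ATAC (61.7% against 68.6%). It was retained more often at those without ATAC (41.7% against 32.6%). The same held at those with HDAC1 (87.3% against 73.0%) and without HDAC1 (48.5% against 37.2%). HDAC3 tag counts at retained peaks were lower after knockdown, with a median log2 ratio of −0.44 (95% CI −0.45 to −0.43) as tag count and −0.074 as tag density, since the peaks of the knockdown library were narrower. The share of all HDAC3 tags lying in peaks was 7.63% in the control and 5.08% after knockdown, a log2 ratio of −0.59. A general fall in occupancy therefore cannot be told apart from a difference in enrichment. Peaks with HOXB13 fell more than those without, with medians of −0.49 and −0.42 (difference −0.079, 95% CI −0.097 to −0.057). Most of this went with peak strength, as the standardised difference was −0.028. Random sets matched on strength, drawn from all retained peaks and thus also from those with HOXB13, had a median of −0.47. The median of peaks with HOXB13 lay at percentile 0.025 of those sets. By HOXB13 strength the median went from −0.43 to −0.57. The retention difference was −6.16 percentage points in the better-scoring 50% of every list, 0.867 with equal numbers of peaks and 2.73 with only HOXB13 peaks lost after knockdown, so its direction depended on which peaks were counted.

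**Figure D3:**
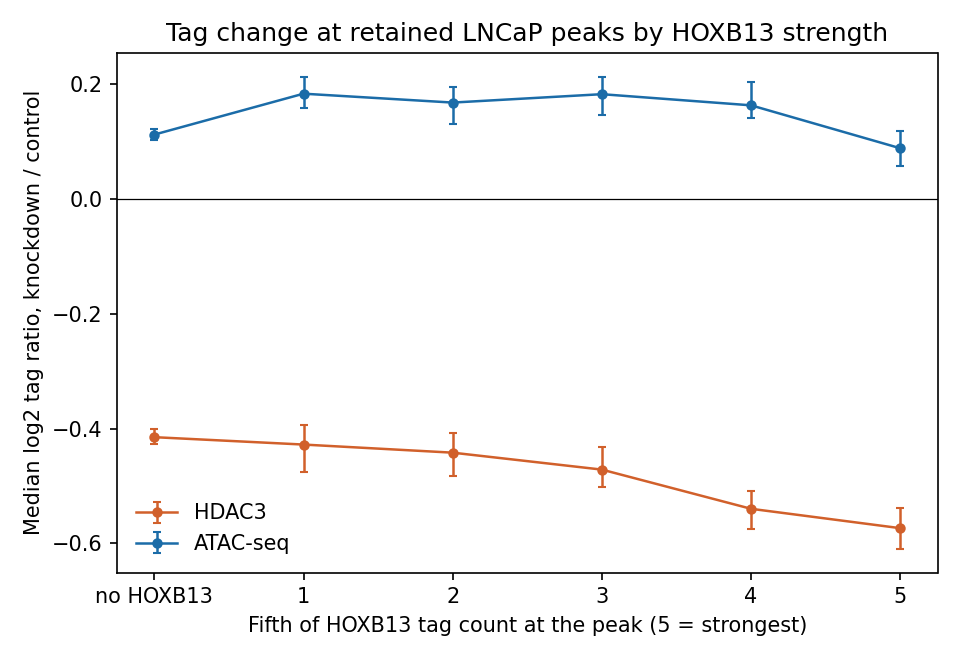
Median log2 ratio of normalized tag counts, knockdown over control (y axis), at retained LNCaP HDAC3 and ATAC peaks without a control HOXB13 peak and in 5 equal groups of HOXB13 tag count (x axis), with bootstrap 95% intervals. HDAC3 goes from −0.42 without HOXB13 to −0.57 in the strongest group, and ATAC is 0.11 without HOXB13, 0.16 to 0.18 in the 4 weaker groups and 0.088 in the strongest. Absolute levels include the difference in peak width between libraries, and as tag density the ATAC medians with and without HOXB13 were −0.036 and −0.082.

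Single HDAC3 sites changed far more than the median. The largest falls among peaks called in both libraries were on chromosome 16 at 2570118 to 2570588 (313.0 normalized tags in the control and 13.3 after knockdown; log2 ratio −4.56, 95% CI −5.09 to −4.07) and at 1524825 to 1525295 (300.0 and 15.2; log2 ratio −4.30, 95% CI −4.80 to −3.84). A site on chromosome 7 at 915787 to 916257 carried 3471.6 normalized tags in the control and 268.7 after knockdown (log2 ratio −3.69, 95% CI −3.80 to −3.58), and was called in all 12 lists. Sites on chromosome 17 at 80454917 to 80455387 (312.1 and 27; log2 ratio −3.53) and chromosome 3 at 158519592 to 158520062 (282.9 and 28.1; log2 ratio −3.33) followed. All 5 also had an HDAC1 peak and a control ATAC peak, and 2 of them had a control HOXB13 peak. Of the 126 retained peaks with a log2 ratio of −2 or below 54.8% had an HDAC1, 74.6% an ATAC and 38.9% a HOXB13 peak, against 33.0%, 58.3% and 38.3% of all retained peaks, without matching on strength. The largest rises were smaller, led by chromosome 11 at 74456840 to 74457310 (12.5 and 66.1; log2 ratio 2.40, 95% CI 1.81 to 3.04) and chromosome 6 at 153603375 to 153603845 (8.35 and 25.1; log2 ratio 1.59, 95% CI 0.82 to 2.43). All 5 of the largest rises had a HOXB13 peak in the control and in the knockdown library, whereas a control HOXB13 peak lay at 44.8% (95% CI 33.5 to 56.6) of the 67 peaks with a log2 ratio of 1 or above and at 38.3% of all retained peaks. The log2 ratio of the peak widths was −0.37, the most that a flat signal would lose. How much of each of these log2 ratios came from the difference in width was not measured. A peak on chromosome 8 at 102596824 to 102597294 (234.2 normalized tags, 95% CI 214.2 to 255.5) was called in the control HDAC3 library and not after knockdown. Others among the strongest peaks called in 1 HDAC3 library alone lay on the mitochondrial sequence, on unplaced sequences or in regions called in 4 to 8 of the 12 lists.

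Chromatin accessibility was compared in the same way. About as many control ATAC peaks were called again after knockdown as were not, with 50.0% retained (95% CI 49.5 to 50.5), and 38.1% of the knockdown peaks were new. Retention was 20.9% in the weakest and 81.5% in the strongest 10% of control peaks. The share of tags in peaks was only 2.46% in the control and 2.38% after knockdown. Without replicates the overlap that unchanged ATAC libraries would give is not known, so a peak not called again need not be a closed site. Accessible sites bound by HOXB13 were retained more often: 57.0% were retained with HOXB13 and 47.5% without, a difference of 9.46 percentage points (95% CI 8.31 to 10.6), or 8.63 at equal ATAC strength (7.65 to 9.72). New peaks were likewise less common among knockdown ATAC peaks with a control HOXB13 site, 32.3% against 40.3% (difference −8.01, 95% CI −9.21 to −6.80). At retained peaks the median log2 tag ratio was 0.16 with HOXB13 and 0.11 without (difference 0.046, 95% CI 0.030 to 0.064; percentile 99.965 of matched sets), which became 0.025 standardised for peak strength and 0.020 with equal numbers of peaks (95% CI 0 to 0.044). In the strongest HOXB13 group the median was 0.088, below that of peaks without HOXB13. For the whole list the direction depended on peak width, since over all retained peaks the median was 0.12 as tag count and −0.070 as tag density. The retention difference at equal ATAC strength was 10.6 percentage points at the weakest of 5 groups of HOXB13 sites and 6.25 at the strongest. In the better-scoring 50% of the lists the retention difference was 4.38 and the difference in gains −2.73 percentage points, and with equal numbers of peaks the retention difference was 6.0.

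The largest ATAC rise was on chromosome 11 at 9386024 to 9386120 (3.04 and 13.0 normalized tags; log2 ratio 2.10, 95% CI 1.07 to 3.22) and the largest fall on chromosome 6 at 72113329 to 72113425 (13.6 and 4.32; log2 ratio −1.65, 95% CI −2.74 to −0.69). The second of these had HOXB13, HDAC1 and HDAC3 peaks in the control. None of the 5 largest rises and 1 of the 5 largest falls had a control HOXB13 peak. At a median of 19 tags per control peak and 15 per knockdown peak, changes at single sites were measured with wide intervals. These sites were picked as the most extreme among the retained peaks. Their intervals, not adjusted for that choice, do not by themselves show a change beyond counting error.

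In PC-3, acetylation of H3K27 was compared between control and knockdown at regions with and without a PC-3 HOXB13 peak. H3K27ac regions had the largest retained share of the 4 knockdown comparisons, with 79.4% of the control regions retained (95% CI 79.0 to 79.7) and 19.9% of the knockdown regions new. That ranking is not like for like, because these stitched regions (median width 1784 bp in the control) overlap more easily than the narrower fixed-width LNCaP peaks. The new share was 36.8% with centres within 500 bp and 39.2% in the better-scoring 50% of the lists. Normalized tag counts at retained loci had a median log2 ratio of 0.27, with 70.1% of loci above 0, and the median ratio of tag densities was 0.20. The share of all tags lying in regions was 38.9% in the control and 46.2% after knockdown, a log2 ratio of 0.25 between the libraries, and 51.4% of loci lay above that ratio, so a rise in acetylation cannot be told apart from a difference in enrichment. The ratio was higher at loci with HOXB13 (0.31) than at those without (0.21), a difference of 0.097 (95% CI 0.083 to 0.11) at percentile 100 of matched sets, with 0.078 as tag density and 0.039 (0.019 to 0.057) in the better-scoring 50% of the lists. Summed over regions, the normalized tags per kb were 32.2 and 37.6, with 120.5 and 122.8 Mb covered.

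Regions with HOXB13 were retained at 92.9% and those without at 68.6%, a difference of 24.3 percentage points (95% CI 23.7 to 25). Regions with HOXB13 were also stronger, and at equal H3K27ac strength the difference was 6.61 points, with 7.19 in the better-scoring 50% of the lists. The value at equal strength is an average weighted to strong regions, which were almost all retained in both classes. In the weakest 10% of regions retention was 58.5% with HOXB13 and 34.4% without. New regions were fewer among those with HOXB13 (12.9% against 26.4%, difference −13.5 points, 95% CI −14.2 to −12.8), a direction that turned at equal strength to 0.844 points, and the difference was −1.47 in the better-scoring 50%. Loci were ranked by tags summed over regions whose widths were called separately in each library, so the sums follow the widths. Highest in this ranking were chromosome 9 at 41911251 to 41915813 (18.7 normalized tags over 1560 bp and 149.4 over 4562 bp; log2 ratio of tag densities 1.45) and chromosome 4 at 166603032 to 166606814 (11.4 over 1000 bp and 77.6 over 3782 bp; 0.85), both with a PC-3 HOXB13 peak. Lowest were chromosome 12 at 29491830 to 29497240 (78.2 over 5410 bp and 10.4 over 1000 bp; −0.47) and chromosome 10 at 79557138 to 79564488 (104.9 over 7288 bp and 14.1 over 1293 bp; −0.40), without one. Such a peak lay at 3 of the 5 highest and 1 of the 5 lowest loci, and at 51.8% of all retained regions.

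HOXB13 sites were finally compared between the cell lines. Of the PC-3 HOXB13 peaks 27.2% (95% CI 26.9 to 27.5) were also LNCaP control peaks, 12.9-fold over random placement, and 21.1% of the LNCaP peaks (20.8 to 21.3) were also PC-3 peaks. Sharing rose with strength, from 18.4% of the weakest to 47.2% of the strongest 10% of PC-3 peaks. The PC-3 and LNCaP libraries were made with different HOXB13 antibodies, so cell line and antibody cannot be separated.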

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

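Standardisation of gains and tag changes and tag density were chosen after the data were seen; all other alternatives were planned. Of 122 alternative values for 17 main results, 51 stayed within the main 95% interval, 68 left it without a change of direction and 3 turned direction. Of 88 alternatives for 15 accompanying results 56 left the interval and 1 turned, the median ATAC tag ratio (0.12), which was −0.070 as tag density by the construction of that setting. Values below are given in the order centres within 100 bp (500 bp for H3K27ac), 50% overlap, better-scoring 50% of lists, common tag floor, equal numbers of peaks, with settings inside the interval left out. HOXB13 retention (1.48%) was 0.818, 1.02 and 1.66% under the first 3, 2.73% with equal numbers and 1.38% on autosomes and X. Control sites found were 56.9, 62.7, 75.7 and 52.1% with WT (67.4%) and 53.0, 58.7, 70.0 and 48.3% with G84E (63.2%), the last of each with equal numbers. WT peaks shared with G84E (55.0%) were 46.9, 51.2 and 62.7%, and their median log2 ratio was −0.13, −0.13 and −0.17 under the first 3 and −0.18 as tag density. Over all 5, HDAC3 peaks with HOXB13 (36.1%) were 19.6, 30.8, 32.7, 28.1 and 19.8%, HDAC1 peaks with HOXB13 (10.7%) 3.67, 5.43, 7.68, 7.11 and 2.95%, and PC-3 HOXB13 peaks shared with LNCaP (27.2%) 21.0, 25.1, 25.6, 26.7 and 24.2%. The HDAC3 retention difference (4.57 points) turned to −0.191 when standardised for peak strength and to −6.16 in better-scoring lists, and was 0.867 with equal numbers and 2.73 with only HOXB13 peaks lost after knockdown. The HDAC3 tag difference (−0.079) was −0.028 standardised and −0.098 with equal numbers, and the difference in HDAC3 gains (−20.9 points) was −16.4 standardised and −24.2, −23.0 and −12.4 under the first 3. For ATAC, the retention difference (9.46 points) was 7.82 with 50% overlap, 4.38 in better-scoring lists and 6.0 with equal numbers. The ATAC tag difference (0.046) was 0.025 standardised and 0.020 with equal numbers, and the difference in gains (−8.01) was −6.39 standardised, −6.62 with 50% overlap and −2.73 in better-scoring lists. For PC-3 H3K27ac, the retention difference (24.3 points) was 6.61 standardised, 22.5, 27.5, 7.19, 22.9 and 21.3 over all 5, and 25.5 with HOXB13 peaks shared with LNCaP. The H3K27ac tag difference (0.097) was 0.14 standardised, 0.078 as tag density, 0.081 with close centres, 0.039 in better-scoring lists and 0.14 with HOXB13 peaks shared with LNCaP. The difference in H3K27ac gains (−13.5 points) turned to 0.844 standardised and was −12.6, −17.1, −1.47, −12.6 and −12.3 over all 5. The standardised HDAC3 retention value averages groups of HOXB13 strength from 5.40 to −4.24 points, and the interval of the standardised H3K27ac gain (0.393 to 1.29) excludes 0; the cause of these and the other shifts was not tested. Centring cannot change a difference between classes by construction, and it took the share of WT and G84E peaks with a log2 ratio below −1 from 2.84% to 1.48%. Distances to genes and motif windows were not run. Shares of new or retained peaks over whole lists moved by over 1.5 times for HDAC3 with close centres (47.7% to 21.3% retained, 47.8% to 76.6% new) and for new H3K27ac regions (19.9% to 36.8% with close centres and 39.2% in better-scoring lists). The HDAC3 fold over random placement (15.3) was 31.6, 27 and 44.2 with close centres, better-scoring lists and equal numbers. Depth limits single ATAC sites most (15 tags per median knockdown peak), and no paired analysis was possible because each group held 1 library.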

Other observations

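All tests in this part were chosen after the results were seen. HOXB13 sites common to both cell lines overlapped the other LNCaP lists more often than the remaining sites did. Of the 19250 LNCaP HOXB13 peaks shared with PC-3, 18.4% had an ATAC peak, 26.8% an HDAC3 peak and 5.01% an HDAC1 peak, against 8.11%, 9.83% and 1.12% of the other LNCaP peaks. At equal HOXB13 strength the HDAC3 difference was 11.9 percentage points and the ATAC difference 5.41. WT HOXB13 returned to 84.3% of the shared sites and 62.9% of the others, and G84E to 79.5% and 58.9%, differences of 10.7 and 10.2 points at equal HOXB13 strength. In PC-3 the shared HOXB13 sites carried H3K27ac about as often as the PC-3-specific ones, 35.4% against 34.1%, and 4.21 points less often at equal strength (−4.21).

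As called, HDAC3 peaks and ATAC peaks were lost together to a limited extent. HDAC3 peaks over an ATAC peak that persisted were retained at 71.3% and those over an ATAC peak that was lost at 61.2%, a difference of 10.1 percentage points (95% CI 8.43 to 11.7) and 5.13 at equal HDAC3 strength. The difference was alike with HOXB13 (9.32) and without it (10.7). It was not matched on ATAC strength, and lost ATAC peaks were weaker than retained ones (median normalized tag count 4.43 against 6.37). HDAC3 tag counts showed no joint loss. At retained HDAC3 peaks the median log2 ratio was −0.50 over ATAC peaks that persisted and −0.48 over those lost. Of the 67 retained HDAC3 peaks with a log2 ratio of 1 or above, 37.3% (95% CI 26.7 to 49.3) had a peak in the HOXB13 shRNA library, against 9.91% of all retained peaks, without matching on peak strength.

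Most of the peaks called after HOXB13 knockdown lay away from control HOXB13 sites. Weak peaks near the calling threshold are a candidate explanation, because the lower-ranked 11432 peaks, with a median of 21 tags, were at control HOXB13 sites 1.63-fold over random placement, against 15.5-fold for the top 10%. It stays open, because the same lower-ranked peaks were at ATAC peaks 9.26-fold, HDAC1 peaks 11.9-fold and HDAC3 peaks 5.98-fold over random placement, more than random noise would give. Background in open chromatin also stays open: 7.47% had an ATAC peak, against 10.3% of control HOXB13 peaks, but accessibility below the ATAC calling threshold is not in the lists. Among control ATAC peaks a knockdown peak was 1.69 points less common with control HOXB13 than without (−1.69, 95% CI −2.14 to −1.22), whereas among HDAC1 peaks it was more common (26.3% against 9.83%).

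At retained peaks HDAC3 tags fell more where HOXB13 had been strongest, with a median log2 ratio of −0.57 against −0.42 without HOXB13, but not at HDAC3 peaks with HDAC1 (−0.39 against −0.47). HDAC3 peak strength does not account for all of this, as the strongest HOXB13 group lay at percentile 0.705 of sets matched on strength. Those sets had a median of −0.54. They were drawn from all retained peaks, those with HOXB13 included, so the part that went with strength cannot be read from them. The different counting windows cannot be told apart from a change in occupancy, because the ratio of peak widths (log2 −0.37) exceeds the difference of −0.16 and the lists hold no recount over equal windows. A loss of HDAC3 that follows HOXB13 may contribute: HDAC3 fell by −0.50 where HOXB13 was lost and by −0.35 where it was retained, while HDAC3 peaks without control HOXB13 showed −0.41 and −0.45 for the same split by a knockdown peak. That difference of differences was 0.19 (95% CI 0.12 to 0.26), with 0.091 at HDAC3 peaks with ATAC and 0.15 at those without, but it was not matched on HDAC3 strength and the counting window stays open.

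G84E tags were lower than WT tags at accessible sites beyond the difference elsewhere (−0.32 against −0.10), and as much so at HDAC3 sites without an ATAC peak (−0.14 at equal strength against sites with neither) as at ATAC sites without HDAC3 (−0.14), with −0.12 at control HOXB13 sites but −0.028 (95% CI −0.061 to 0.011) at HDAC1 sites. Peak strength does not account for this, as the difference was −0.15 (95% CI −0.16 to −0.14) over groups of equal mean tag count. More open chromatin background in the WT library would lower the ratio at least as far at accessible sites with HDAC1 as at those without, but at equal strength the ratio was 0.085 higher there (95% CI 0.038 to 0.13), a form of the test that replaced the raw difference (0.14) after that had been seen. Background stays open, because the same split by HDAC3 gave −0.034 (95% CI −0.055 to −0.0068), the direction it predicts. Sites with a HOXB13 shRNA peak had less of a deficit at equal strength (0.095, 95% CI 0.054 to 0.12). That goes against background only if those shRNA peaks are background themselves, which is not known. The split by control HOXB13 decides nothing, as it went from −0.16 to −0.049 at equal strength (95% CI −0.14 to 0.043). A different amount of expressed protein cannot be told apart from a different preference of the variant, because protein was not measured here and the share of tags in peaks differed by −1.48 percentage points.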
